A study of Homo sapiens with 60 samples.

How the data were processed

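Gene expression was measured by RNA sequencing in A549 cells, an established human non-small cell lung carcinoma line, 24 h after treatment with 1 of 8 herbal extracts at 3 doses or with DMSO vehicle. Strand-specific mRNA libraries were read as 100 bp pairs. Per the labels, the authors checked reads with FastQC 0.11.9, trimmed them with Trim Galore 0.6.5, aligned them with STAR 2.7.3a to hg38 (GRCh38) and counted genes with RSEM 1.3.3. The annotation release used for counting was not given in the sources used here. The deposited table holds RSEM expected counts per gene, not normalised and not on a log scale, for 60675 Ensembl gene IDs. Of its non-zero values in the columns analysed, 24.4% were not whole numbers. It has 269 value columns, of which 60 belong to this series. The other 209 columns were not used in any step.

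The 60 libraries formed 25 groups. Library totals ran from 17.51 to 38.54 M (mega) counts, with a median of 23.54 M. Expected counts were rounded to whole numbers. Gene symbols were given for 56558 IDs, and gene lengths and positions came from GENCODE 29 on GRCh38 (57055 IDs with a length).

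The labels number the extracts in sets of 2, and each fit held both extracts of 1 set and the 3 vehicle libraries. That gave 3 fits with replicated extracts: Sayeok-tang with Bojungikgi-tang, fresh with dried ginger, and Pinellia with Scutellaria. Genes with low counts were removed with filterByExpr of edgeR 4.0.16 (minimum count 10), libraries were scaled by TMM, and each gene was tested with edgeR's quasi-likelihood F-test (robust glmQLFit, 1 mean per group, R 4.3.3). P-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison, and a gene was called at an adjusted p under 0.05. There were 28 comparisons, 8 of them at the high dose against vehicle or between related extracts. Errors of log2 changes are standard errors from the fit, and errors of CPM (counts scaled to the TMM-adjusted library total) are standard deviations between libraries.

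Gene groups were tested as 30 fixed lists (645 of their 646 members were in the table), covering stress, metabolic, cell cycle and inflammatory pathways and markers of other cell types. The test was camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a comparison. Each list was also tested with a correlation estimated from the data, and counts of members past the test were given over all genes and adjusted over the list alone.

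Coptis and Zizyphus had 1 library per dose. A fit of all 60 libraries, with the spread pooled from the replicated groups, tested these as an alternative. The values given rest on a size rule instead: a log2 ratio to the vehicle mean of at least 1 in size (2-fold, after adding 0.5 CPM), outside the range of the 3 vehicle libraries, in genes with a mean of at least 5 CPM. Medians of lists were set against 10000 random lists of genes of the same size.

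Named genes were taken by a rule: per main comparison the 6 higher and 6 lower genes with the largest log2 change among those past the test, with a mean of at least 5 CPM and no overlap between the libraries of the groups, and the up to 3 members with the lowest p of each list that had a camera call or at least 3 members past the test. Fewer were taken at other doses, and CYP1A1, HMOX1, CDKN1A, FKBP5, HMGCS1 and DDIT3 were followed throughout. Samples, groups, the tests of the 28 comparisons, lists, the naming rule and all alternatives but the trend removal were fixed before the data were examined. Tests of differences between extracts in their dose change, overlaps between extracts and those tests of the closing section that are named so there were chosen afterwards.

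The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical in part. The labels put all 60 libraries in 1 named batch, but the vehicle libraries and the extract libraries carry different set numbers. A difference in handling between them would therefore be confounded with treatment in every comparison with vehicle. The sample labels give a DMSO concentration for the vehicle alone. A difference in solvent would therefore be confounded in the same way. Comparisons between doses of 1 extract do not involve the vehicle libraries' levels.

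The test was run on simulated data, negative binomial counts with the fitted spread of each gene and known changes added. It recovered 86.4% of 2-fold and 62.7% of 1.25-fold changes in a Sayeok-tang design, with 3% of calls false, and 75.8% and 53.7% in a Scutellaria design, with 9.1% of calls false. With no change added, edgeR's test called 0 genes in each of the 3 simulated designs.

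Alternatives were DESeq2 1.42.0, relative log expression size factors, no filter on low counts, 1 fit of all 60 libraries, the replicate number as a block, leaving out each library in turn and, chosen after seeing the data, removal of gene length and GC trends from each library. Tables and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Libraries of replicates 2 and 3 of Coptis and Zizyphus and of replicate 1 of Bojungikgi-tang were not analysed here, since the series lists none, and the positive control named in the series text has no library in this series.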

Results

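RNA-seq libraries were made from A549 lung carcinoma cells 24 h after addition of herbal extracts or vehicle. The 60 libraries comprised 3 vehicle libraries and 8 extracts at a high, medium and low dose. Sayeok-tang and Bojungikgi-tang, herbal formulas extracted in water, were given at 500, 100 and 20 µg/mL, with n = 3 and n = 2 libraries per dose. Fresh ginger (Zingiberis Rhizoma Recens), dried ginger (Zingiberis Rhizoma) and Pinelliae Tuber, extracted in 70% ethanol, were given at the same doses with n = 3. Scutellariae Radix in 70% ethanol was given at 190, 38 and 7.6 µg/mL with n = 3. Coptidis Rhizoma (110, 22 and 4.4 µg/mL) and Zizyphi Fructus (500, 100 and 20 µg/mL), both in 70% ethanol, had 1 library per dose. The sample labels and the series text give different DMSO concentrations for the vehicle, and the sources used here do not settle which applied. Totals were 17.51 to 38.54 M (mega) counts per library, with 22437 to 24471 genes detected. Mitochondrial transcripts took 8.29 to 15.9% of counts, with a mean of 9.05 ± 0.417% in vehicle (SD, n = 3). Positions are on GRCh38, and log2 changes are given ± SE and CPM ± SD.

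**Figure D1:**
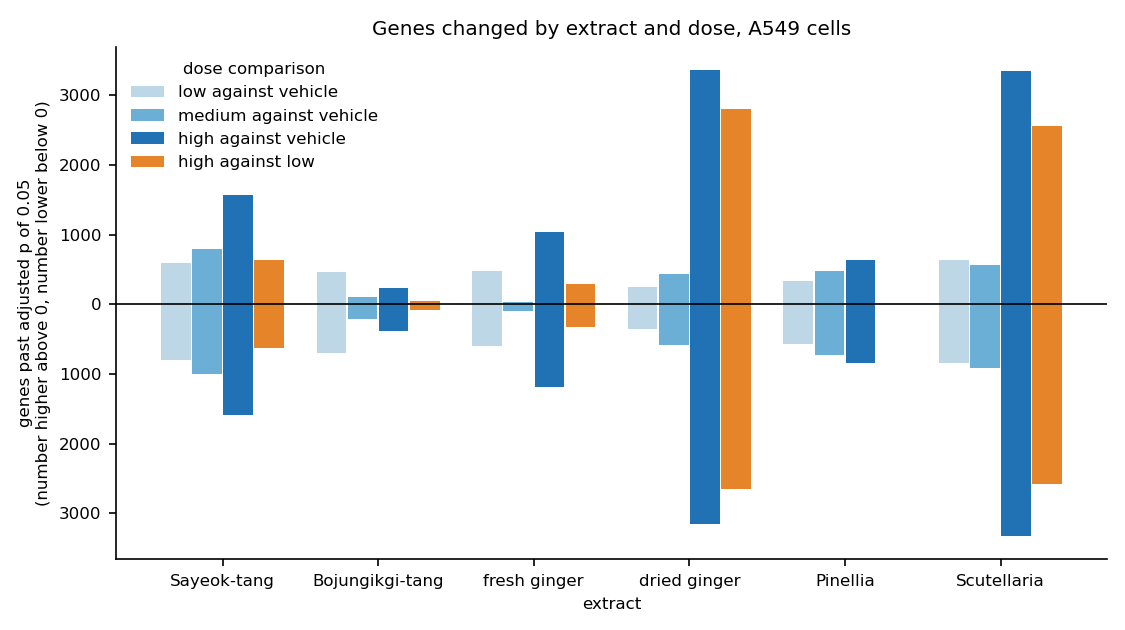
Number of genes called higher (bars above 0) and lower (bars below 0) in each comparison, for 6 replicated extracts at the low, medium and high dose against vehicle and at the high against the low dose. Calls reached 6514 for dried ginger and 6678 for Scutellaria at the high dose, and the high and low doses of Pinellia differed in 11 genes.

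Sayeok-tang at 500 µg/mL was compared with vehicle to find the genes that respond to the formula. The secreted BMP antagonist GREM1 (ENSG00000166923, chromosome 15, 32717974 to 32745107) rose by 1.54 ± 0.08 on the log2 scale, from 5.03 ± 0.19 to 14.7 ± 0.257 CPM (n = 3 each, adjusted p = 1.28e-16). CYP1B1 (ENSG00000138061, chromosome 2, 38066973 to 38109902), a monooxygenase induced through the aryl hydrocarbon receptor (AhR), rose from 56.0 ± 2.12 to 140 ± 4.82 CPM (log2 change 1.32 ± 0.04, adjusted p = 1.25e-24). TIPARP (ENSG00000163659, chromosome 3, 156673235 to 156706770), an AhR target that represses the receptor, rose by 1.15 ± 0.04. NR4A1 (ENSG00000123358, chromosome 12, 52022832 to 52059507), an orphan nuclear receptor, fell by 1.00 on the log2 scale, from 38.1 ± 1.37 to 19.1 ± 0.614 CPM (adjusted p = 5.53e-17). In all, 1571 genes were higher and 1593 lower of 16723 tested, 73 of them by at least 2-fold, and the median size of the called log2 changes was 0.202.

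Among the fixed lists, NF-kB and inflammation had 17 members higher and 1 lower of 20 (17 and 1 adjusted over the list alone), with a median log2 change of 0.58 (camera adjusted p = 2.27e-41). Its chemokines CXCL8 (2.56 ± 0.16), CXCL1 (2.60 ± 0.17) and CXCL5 (ENSG00000163735, chromosome 4, 73995642 to 73998779; 1.03 ± 0.03, 84.9 ± 1.27 to 173 ± 8.74 CPM) rose. Of 25 cholesterol synthesis genes, 18 rose and 1 fell (18 and 1 adjusted over the list alone; adjusted p = 9.25e-23). DHCR7, which catalyses a last step of the pathway, rose by 0.43 ± 0.04, squalene epoxidase SQLE by 0.33 ± 0.03 and HMGCS1 by 0.22 ± 0.03. Of the 27 genes of the ATF4 amino acid response, 18 rose and 1 fell (21 and 2 adjusted over the list alone; adjusted p = 3.34e-17), among them STC2 (0.69 ± 0.05) and the folate enzyme ALDH1L2 (0.76 ± 0.06). AhR targets rose in 4 of 8 members and fell in 1 (4 and 1 adjusted over the list alone), including CYP1A1 (1.79 ± 0.19). Fatty acid synthesis genes rose in 9 of 15 (9 adjusted over the list alone), led by the desaturases SCD (0.48 ± 0.03) and FADS1 (0.46 ± 0.03). Cytosolic heat shock genes fell in 14 of 19 (14 lower and 1 higher adjusted over the list alone). The calls of these 6 lists and of hypoxia and glycolysis (3 higher, 14 lower of 30; 5 and 14 adjusted over the list alone) held with an estimated correlation. Those of the nuclear respiratory chain (20 of 31 lower, 24 adjusted over the list alone) and the cytosolic ribosome (20 of 35 lower, 22 adjusted over the list alone) were lost, with adjusted p = 0.069 and adjusted p = 0.155 with an estimated correlation. Complement C3 rose by 0.90 ± 0.05, and the keratin KRT18 (−0.50 ± 0.03) and the fibrinogen chain FGB (−0.66 ± 0.03) fell. CDKN1A (−0.09 ± 0.03, adjusted p = 0.0547), FKBP5 (0.06 ± 0.05) and DDIT3 (−0.13 ± 0.09) did not pass the test.

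Between the high and low doses of Sayeok-tang 638 genes were higher and 630 lower at the high dose. GREM1 (1.37 ± 0.08) and the cytokine IL32 (1.35 ± 0.10) rose and the imprinted RNA H19 fell by 1.08 on the log2 scale. Cholesterol synthesis rose in 22 of 25 members (22 adjusted over the list alone; adjusted p = 1.74e-44), and NF-kB and inflammation in 16 of 20 with 1 lower (17 and 1 adjusted over the list alone). At 100 µg/mL 799 genes were higher and 1003 lower than in vehicle, and at 20 µg/mL 597 and 795. CYP1A1 rose at 100 µg/mL (1.04 ± 0.21, adjusted p = 9.39e-04) and was 0.02 ± 0.24 at 20 µg/mL. HMGCS1 was −0.01 ± 0.03 and −0.02 ± 0.04 at these doses, neither past the test. The medium-dose total of 1802 genes was 836 without library 1 of that dose, 1055 without its library 3 and 1090 without vehicle library 3. The low-dose total of 1392 was 797 without library 3 of that dose and 766 without vehicle library 3.

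Bojungikgi-tang, compared with vehicle for the same question, had 2 libraries per dose. At 500 µg/mL CYP1B1 rose from 56.0 ± 2.12 to 97.6 ± 6.22 CPM (n = 3 and n = 2, log2 change 0.81 ± 0.04, adjusted p = 1.34e-15), and TIPARP by 0.65 ± 0.05. The chemokines CXCL1 (1.63 ± 0.21) and CXCL8 (1.45 ± 0.20) rose and so did complement C3 (0.50 ± 0.05). NR4A1 fell by 0.56 on the log2 scale (adjusted p = 2.38e-08), and the stress-inducible chaperone HSPA1A (ENSG00000204389, chromosome 6, 31815464 to 31817946) fell from 342 ± 15.6 to 262 ± 10.2 CPM (adjusted p = 0.00211). In all, 233 genes were higher and 389 lower. The high-dose total of 622 was 203 without library 2 of that dose and 290 without library 3, each of which left 1 library, and 367 in a fit of all 60 libraries.

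In Bojungikgi-tang at 500 µg/mL, NF-kB and inflammation rose in 9 of 20 members (12 adjusted over the list alone; camera adjusted p = 4.85e-18), and AhR targets in 4 of 8 with 1 lower (5 and 1 adjusted over the list alone; adjusted p = 1.49e-16). Cytosolic heat shock genes fell in 10 of 19 (14 adjusted over the list alone; adjusted p = 9.62e-14), and hypoxia and glycolysis in 5 of 30 (9 adjusted over the list alone), with the glycolytic enzyme ENO1 at −0.16 ± 0.03. These 4 calls held with an estimated correlation. The cytosolic ribosome (11 of 35 lower, 18 adjusted over the list alone) was lost with adjusted p = 0.247 with an estimated correlation. Of 25 cholesterol synthesis genes 0 were called by edgeR over all genes or over the list alone, and camera gave adjusted p = 0.768. HMOX1 (0.03 ± 0.04), HMGCS1 (0.07 ± 0.04), FKBP5 and DDIT3 did not pass. Heat shock genes were also lower than in vehicle at the low dose of Pinellia (4 lower and 1 higher of 19, camera adjusted p = 6.22e-04). That Pinellia call was lost with an estimated correlation (adjusted p = 0.228). A fall of this list against vehicle was thus not confined to high doses.

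Between 500 and 20 µg/mL of Bojungikgi-tang 43 genes were higher and 76 lower, with CYP1B1 at 0.61 ± 0.05, GREM1 at 0.59 ± 0.11, NR4A1 at −0.65 ± 0.06 and H19 at −0.66 ± 0.09, all past the test. That total of 119 was 75 and 43 without high-dose library 2 and 3, and 24 and 30 without low-dose library 2 and 3. It was 197 with no filter on low counts and 180 after an abundance-dependent trend was removed. The 100 µg/mL dose had 111 genes higher and 210 lower than vehicle, and the 20 µg/mL dose 461 and 700. The medium-dose total of 321 was 15 without its library 2, 197 without its library 3, 172 without vehicle library 2, 107 in a fit of all 60 libraries, 544 with no filter on low counts and 511 after 1 trend per library was removed. The low-dose total of 1161 was 391 without its library 2, 205 without its library 3, 767 without vehicle library 3 and 759 in a fit of all 60 libraries. The cytosolic ribosome fell at the low dose in 22 of 35 members (32 adjusted over the list alone; adjusted p = 2.39e-34), a call that held with an estimated correlation, and it was lower at the low dose of the other replicated extracts too.

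Set against each other at 500 µg/mL, the formulas differed in 343 genes, 183 higher and 160 lower in Sayeok-tang. Cholesterol synthesis was higher in Sayeok-tang in 17 of 25 members (23 adjusted over the list alone; median log2 difference 0.26, camera adjusted p = 7.17e-53), with DHCR7 at 0.36 ± 0.04 and FDFT1, the squalene synthase, at 0.32 ± 0.03. NF-kB and inflammation was higher in 8 of 20 with 1 lower (15 and 1 adjusted over the list alone), with CXCL5 at 173 ± 8.74 against 115 ± 0.246 CPM (n = 3 and n = 2). The ATF4 list was higher in 11 of 27 (19 adjusted over the list alone), with TRIB3 at 0.41 ± 0.05 and STC2 at 0.42 ± 0.05. GREM1 (0.93 ± 0.09) was also higher, and H19 (−0.60 ± 0.09), KRT4 (−0.57 ± 0.08) and FGB (−0.54 ± 0.04) lower. The cholesterol, NF-kB and ATF4 calls held with an estimated correlation. That of mitosis, with 0 of 30 members called by edgeR, was lost with adjusted p = 0.0581 with an estimated correlation. The total of 343 was 199 and 183 without Bojungikgi-tang library 2 and 3.

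Fresh ginger at 500 µg/mL was compared with vehicle and with dried ginger, which the series set side by side at equal doses. Against vehicle CYP1B1 rose from 56.6 ± 2.15 to 125 ± 3.56 CPM (n = 3 each, log2 change 1.15 ± 0.04, adjusted p = 1.77e-17). The stress-responsive gene NIBAN1 (ENSG00000135842, chromosome 1, 184790724 to 184974550) rose by 1.10 ± 0.08, and STC2 (ENSG00000113739, chromosome 5, 173314713 to 173329503), a secreted glycoprotein of the ATF4 response, rose from 28.8 ± 1.05 to 54.9 ± 2.43 CPM. The list of zinc- and copper-binding metallothioneins, which includes the zinc exporter SLC30A1, rose in 4 of 5 members (4 adjusted over the list alone; camera adjusted p = 8.85e-08), with MT1X (ENSG00000187193, chromosome 16, 56682424 to 56684196) going from 11.6 ± 1.22 to 20.1 ± 1.84 CPM and MT1F from 1.45 ± 0.22 to 4.61 ± 0.319 CPM. SLC30A1 rose by 0.21 ± 0.04, and MT1A was −0.01 ± 0.20, not past the test. NR4A1 fell by 0.97 and NR4A3 by 1.03 on the log2 scale. In all, 1033 genes were higher and 1191 lower of 16629, 53 of them by at least 2-fold. The total of 2224 was 1391 and 1403 without high-dose library 1 and 2 and 1319 without vehicle library 3.

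The ATF4 amino acid response rose with fresh ginger in 22 of 27 members, with 1 lower (22 and 1 adjusted over the list alone; adjusted p = 7.36e-46), including ALDH1L2 (0.99 ± 0.07) and asparagine synthetase ASNS (0.58 ± 0.04). The ER unfolded protein response rose in 13 of 22 with 2 lower (14 and 2 adjusted over the list alone), with HYOU1 at 0.30 ± 0.04. TGF-beta and mesenchymal genes fell in 13 of 27 with 3 higher (17 and 3 adjusted over the list alone; adjusted p = 6.97e-17). PMEPA1, a TGF-beta target, fell by 0.62, and the collagen genes COL5A1 and COL4A1 fell by 0.61 and 0.53 on the log2 scale. Mitosis genes fell in 16 of 30 with 1 higher (18 and 1 adjusted over the list alone; adjusted p = 4.62e-11), with cyclin B1 (CCNB1, ENSG00000134057, chromosome 5, 69167010 to 69178245) falling from 243 ± 4.79 to 199 ± 6.8 CPM. CCNB1 was also called lower than in vehicle at the low dose of all 6 replicated extracts. Drug metabolism and transport rose in 6 of 18 with 1 lower (7 and 1 adjusted over the list alone). These calls and that of the metallothionein list held with an estimated correlation, as did AhR targets (4 higher, 1 lower of 8; 4 and 1 adjusted over the list alone), fatty acid synthesis (7 of 15 higher, 8 adjusted over the list alone), heat shock (11 of 19 lower, 14 adjusted over the list alone), and hypoxia and glycolysis (2 higher, 9 lower of 30; 3 and 10 adjusted over the list alone). Cholesterol synthesis (5 higher, 2 lower of 25; 8 and 2 adjusted over the list alone) was lost with adjusted p = 0.15 with an estimated correlation. HMGCS1 (0.08 ± 0.04) and FKBP5 (0.00 ± 0.07) did not pass, and DDIT3 rose by 0.29 ± 0.07. Drug metabolism and transport was also higher than in vehicle at the low dose of Pinellia (camera adjusted p = 0.00974). That Pinellia call was lost with an estimated correlation (adjusted p = 0.0559). A rise of this list against vehicle was thus not particular to fresh ginger.

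Between 500 and 20 µg/mL of fresh ginger 286 genes were higher and 324 lower. CHAC1, a glutathione-degrading enzyme of the ATF4 response, rose by 1.16 ± 0.11, MT1X by 1.15 ± 0.12 and CYP1A1 by 1.64 ± 0.19, and H19 fell by 1.14 on the log2 scale. The ATF4 list rose in 23 of 27 members (24 adjusted over the list alone; adjusted p = 2.01e-125) and the metallothionein list, SLC30A1 included, in 4 of 5 (5 adjusted over the list alone; adjusted p = 1.64e-21). The total of 610 was 382 without high-dose library 1 and 1010 in a fit of all 60 libraries. At 100 µg/mL 38 genes were higher and 90 lower than in vehicle, and at 20 µg/mL 473 and 604. CYP1B1 rose by 0.45 ± 0.04 at 100 µg/mL, where the ER unfolded protein response was higher in 5 of 22 members (15 adjusted over the list alone; adjusted p = 5.86e-17). Ceruloplasmin (CP), a copper-carrying oxidase, rose by 0.91 ± 0.12 at 20 µg/mL, and it was called higher at the low dose of all 6 replicated extracts. The medium-dose total of 128 was 81, 600 and 71 without its library 1, 2 and 3, and 52 and 76 without vehicle library 1 and 2. It was 273 by DESeq2, 465 in a fit of all 60 libraries, 299 with no filter on low counts, and 220 and 210 after removal of length and GC trends. The low-dose total of 1077 was 661, 400 and 609 without its library 1, 2 and 3, 597 and 368 without vehicle library 2 and 3, and 2053 in a fit of all 60 libraries.

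Dried ginger at 500 µg/mL changed 3359 genes upward and 3155 downward against vehicle, 381 of them by at least 2-fold. NIBAN1 rose from 10.7 ± 0.733 to 79.9 ± 2.7 CPM (n = 3 each, log2 change 2.90 ± 0.07, adjusted p = 4.21e-22) and STC2 from 28.8 ± 1.05 to 121 ± 3.11 CPM (2.07 ± 0.06). The pseudokinase TRIB3 (ENSG00000101255, chromosome 20, 362835 to 397559) rose from 69.7 ± 5.57 to 203 ± 1.65 CPM, and DDIT3 (ENSG00000175197, chromosome 12, 57516588 to 57521737), which encodes the stress factor CHOP, by 1.09 ± 0.07. The imprinted RNA H19 (ENSG00000130600, chromosome 11, 1995176 to 2001470) fell from 85.7 ± 7.53 to 14.4 ± 1.2 CPM (adjusted p = 3.17e-22), and the keratin KRT4 (ENSG00000170477, chromosome 12, 52806549 to 52814551) fell by 2.37 on the log2 scale. GREM1 (2.07 ± 0.08), CYP1B1 (1.81 ± 0.04), CYP1A1 (2.63 ± 0.16) and CXCL5 (1.39 ± 0.04) rose, and the fibrinogen chains FGB (−1.83 ± 0.05) and FGA (−1.70 ± 0.05) fell.

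All 30 mitosis genes fell with dried ginger (30 adjusted over the list alone; camera adjusted p = 1.38e-53), with CCNB1 going from 243 ± 4.79 to 137 ± 3.63 CPM and the mitotic kinesin KIF20A at −0.97 ± 0.05. DNA replication genes fell in 28 of 32 (28 adjusted over the list alone), with thymidine kinase TK1 at −0.70 ± 0.06. Cholesterol synthesis fell in 21 of 25 with 1 higher (21 and 1 adjusted over the list alone; adjusted p = 6.64e-13): HMGCS1 (ENSG00000112972, chromosome 5, 43289395 to 43313512), the HMG-CoA synthase, went from 205 ± 8.83 to 134 ± 5.8 CPM. The ATF4 list rose in 25 of 27 (26 higher and 1 lower adjusted over the list alone; adjusted p = 9.33e-75). NF-kB and inflammation rose in 18 of 20 (18 adjusted over the list alone; adjusted p = 3.95e-23), with CXCL8 (ENSG00000169429, chromosome 4, 73740506 to 73743716) at 2.85 ± 0.19. Heat shock genes fell in 16 of 19 (17 adjusted over the list alone), with HSPA1A at −0.80 ± 0.04 and HSP90AB1 at −0.48 ± 0.04. These 6 calls held with an estimated correlation, as did AhR targets (5 higher, 1 lower of 8; 5 and 1 adjusted over the list alone) and hypoxia and glycolysis (8 higher, 16 lower of 30; 8 and 17 adjusted over the list alone). Immediate early genes (15 higher, 5 lower of 23; 15 and 5 adjusted over the list alone) were lost with adjusted p = 0.138 with an estimated correlation, and extracellular complement and coagulation (5 higher, 7 lower of 21; 5 and 7 adjusted over the list alone) with adjusted p = 0.121. PPAR and fatty acid oxidation rose in 5 of 15 with 1 lower (5 and 1 adjusted over the list alone), including the lipid droplet coat PLIN2 (1.01 ± 0.07), and was lost with adjusted p = 0.233 with an estimated correlation. FKBP5 did not pass.

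Between the high and low doses of dried ginger 2800 genes were higher and 2654 lower, with NIBAN1 at 2.90 ± 0.07, H19 at −2.59 ± 0.06, DDIT3 at 1.22 ± 0.07 and HMGCS1 at −0.60 ± 0.04. Mitosis fell in 30 of 30 members (30 adjusted over the list alone) and cholesterol synthesis in 20 of 25 (20 lower and 1 higher adjusted over the list alone). At 100 µg/mL 440 genes were higher and 581 lower than in vehicle, and at 20 µg/mL 243 and 356. CYP1A1 rose at both (1.55 ± 0.18 and 0.73 ± 0.20), and HMGCS1 was −0.01 ± 0.04 and 0.00 ± 0.04, not past the test. At 100 µg/mL the AhR targets rose in 4 of 8 (4 higher and 1 lower adjusted over the list alone; adjusted p = 7.84e-18) and NF-kB and inflammation in 5 of 20 (8 higher and 1 lower adjusted over the list alone; adjusted p = 1.01e-05), and both calls held with an estimated correlation. The medium-dose total of 1021 was 672, 456 and 597 without its library 1, 2 and 3, 680 and 417 without vehicle library 2 and 3, and 1800 in a fit of all 60 libraries. The low-dose total of 599 was 197, 312 and 250 without its library 1, 2 and 3, 321 and 137 without vehicle library 2 and 3, 1402 in a fit of all 60 libraries, and 976 with no filter on low counts.

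At 500 µg/mL the gingers differed in 3745 genes, 1874 higher and 1871 lower in fresh ginger, without using the vehicle libraries' levels. HMGCS1 was 217 ± 5.87 CPM with fresh and 134 ± 5.8 CPM with dried ginger (n = 3 each, log2 difference 0.69 ± 0.04, adjusted p = 1.13e-12), and cholesterol synthesis was higher with fresh ginger in 22 of 25 members (22 adjusted over the list alone; camera adjusted p = 1.27e-33). MT1X was 20.1 ± 1.84 against 9.07 ± 1.34 CPM, and the metallothionein list was higher with fresh ginger in 4 of 5 (4 adjusted over the list alone), SLC30A1 among the 4. Mitosis was higher in 30 of 30 (30 adjusted over the list alone) and heat shock in 16 of 19 (16 adjusted over the list alone). The ATF4 list was lower with fresh ginger in 25 of 27 (25 adjusted over the list alone), with NIBAN1, a gene outside that list, at −1.80 ± 0.07, STC2 at −1.14 ± 0.06 and TRIB3 at −0.91 ± 0.05. NF-kB and inflammation was lower in 19 of 20 (19 adjusted over the list alone), with CXCL5 at 109 ± 3.3 against 225 ± 0.925 CPM. All these list calls held with an estimated correlation. HMOX1, which encodes a heme-degrading enzyme, had a difference of 0.01 ± 0.04 (adjusted p = 0.878).

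At 100 µg/mL the gingers differed in 80 genes, 48 higher and 32 lower in fresh ginger. KRT4 was 30.5 ± 0.728 against 20.6 ± 0.335 CPM (adjusted p = 6.31e-07), and the signalling kinase gene IRAK2 was lower with fresh ginger (−0.59 ± 0.08). AhR targets were lower in 3 of 8 (4 adjusted over the list alone; adjusted p = 7.6e-12), with CYP1A1 at −0.91 ± 0.18, and that call held with an estimated correlation. The total of 80 was 220 without fresh ginger library 1, and 50, 33 and 38 without dried ginger library 1, 2 and 3. It was 151 by DESeq2, 252 in a fit of all 60 libraries, 244 with no filter on low counts and 123 after 1 trend per library was removed. At 20 µg/mL edgeR called 0 genes, with 471 of 16629 at an unadjusted p under 0.05, fewer than a share of 0.05 would give. There DESeq2 called 2, a fit of all 60 libraries 1, edgeR without the filter on low counts 13, and edgeR after either trend removal 3. CYP1A1 differed by −0.80 ± 0.20 at that dose (adjusted p = 0.814).

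**Figure D2:**
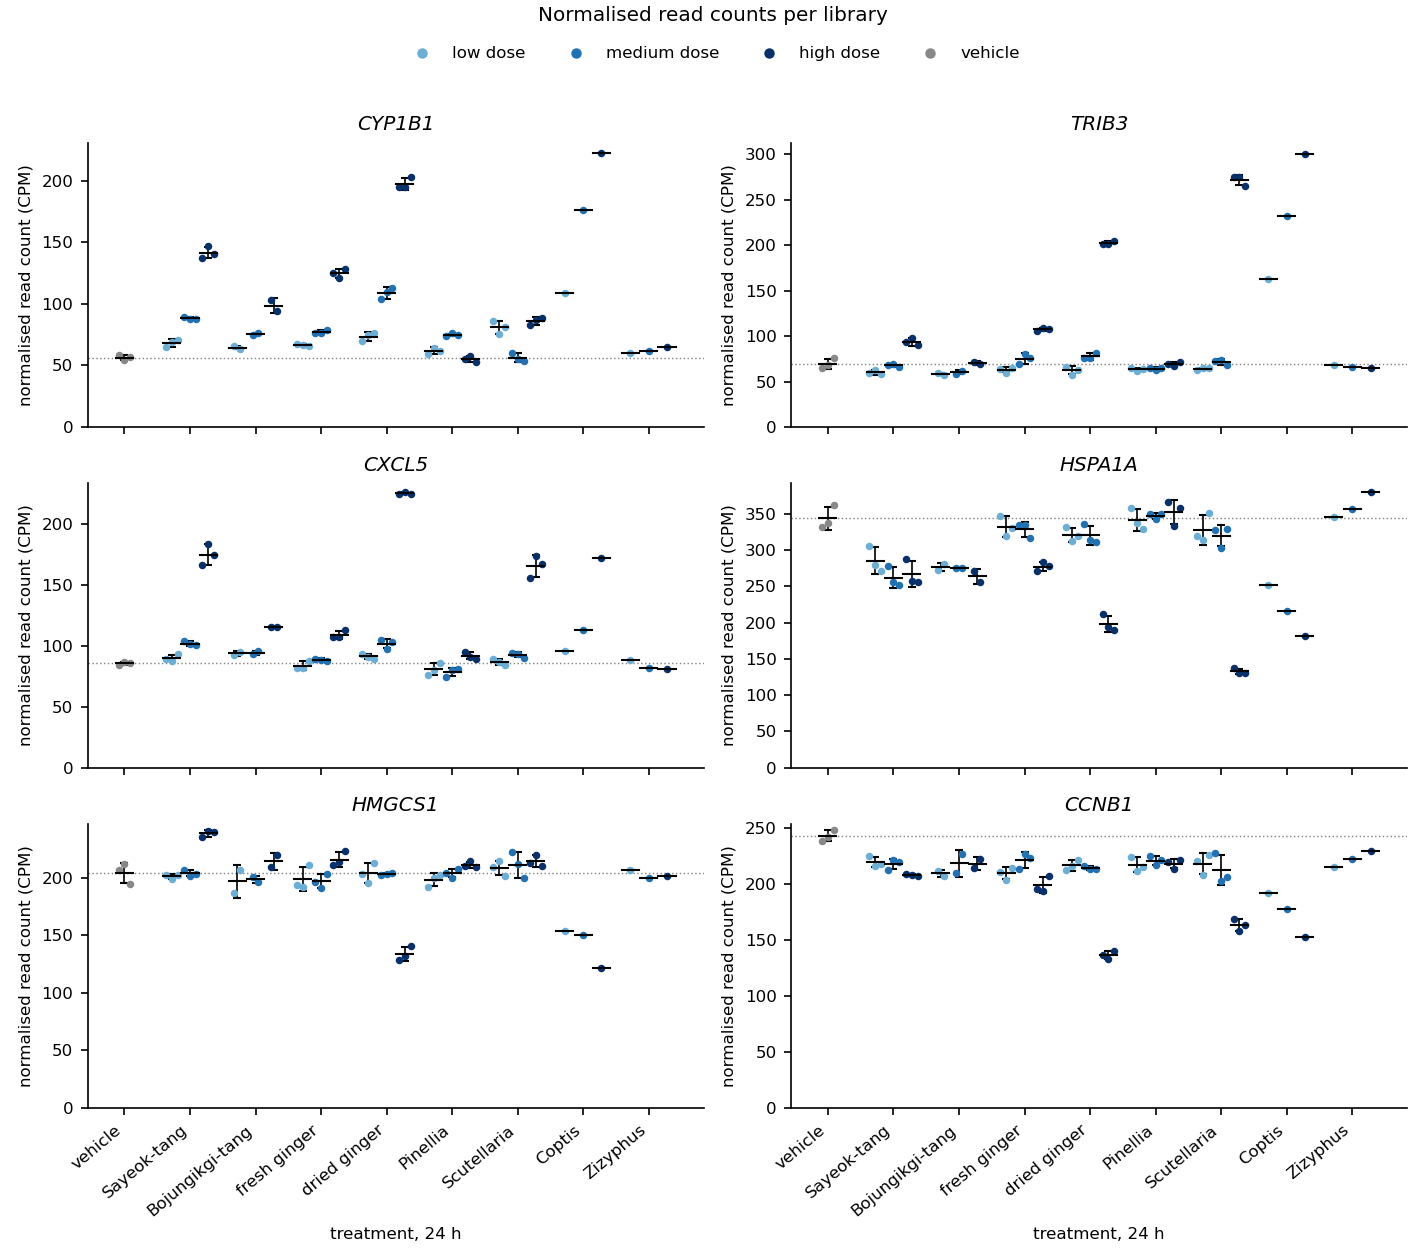
Level of 6 genes in each library (points, CPM with TMM factors over all 60 libraries) for each extract and dose, where black lines are group means, error bars are SD where n is above 1 and the dotted line is the vehicle mean. HMGCS1 lay lower with dried than with fresh ginger at the high dose, and HSPA1A fell with Scutellaria.

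Scutellaria at 190 µg/mL changed 3355 genes upward and 3323 downward against vehicle, 212 of them by at least 2-fold. TRIB3 rose from 70.0 ± 5.6 to 274 ± 5.77 CPM (n = 3 each, log2 change 1.97 ± 0.04, adjusted p = 6.16e-32), STC2 from 28.9 ± 1.05 to 124 ± 2.11 CPM, and NIBAN1 by 2.44 ± 0.06. DDIT3 rose by 1.84 ± 0.07, and TSC22D3, a leucine zipper gene also induced by glucocorticoids, by 1.94 ± 0.07. HSPA1A fell from 347 ± 15.9 to 134 ± 3.87 CPM (adjusted p = 4.33e-19), and the cytosolic chaperone HSP90AA1 by 0.84 on the log2 scale. H19 fell by 1.13 and the cell cycle inhibitor CDKN2C by 1.01 on the log2 scale.

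The ATF4 list rose in 24 of 27 members with Scutellaria (26 adjusted over the list alone; median log2 change 0.99, camera adjusted p = 8.26e-155), with the gluconeogenic enzyme PCK2 going from 37.1 ± 1.06 to 105 ± 2.54 CPM. The ER unfolded protein response rose in 16 of 22 with 2 lower (16 and 2 adjusted over the list alone), with the chaperone HSPA5 at 0.47 ± 0.03 and HERPUD1 at 0.75 ± 0.05. Cytosolic heat shock fell in 17 of 19 (17 adjusted over the list alone; adjusted p = 5.29e-57). Targets of p53 rose in 14 of 24 (14 adjusted over the list alone; adjusted p = 2.79e-06), with GDF15 at 0.93 ± 0.06, the death receptor TNFRSF10B at 0.70 ± 0.03 and the cell cycle inhibitor CDKN1A at 0.42 ± 0.04. Immediate early genes rose in 20 of 23 (20 adjusted over the list alone), with the transcription factor ATF3 going from 8.46 ± 0.678 to 20.1 ± 1.34 CPM. Mitosis fell in 29 of 30 (29 adjusted over the list alone) and DNA replication in 29 of 32 (29 adjusted over the list alone), with AURKA and the endonuclease FEN1 both at −0.59. Cholesterol synthesis rose in 16 of 25 with 2 lower (16 and 3 adjusted over the list alone), with INSIG1, a sterol sensor, at 0.65 ± 0.05, while HMGCS1 was 0.07 ± 0.04 (adjusted p = 0.128). NF-kB and inflammation rose in 14 of 20 with 1 lower (14 and 1 adjusted over the list alone), and epithelial and alveolar genes in 11 of 17 with 2 lower (11 and 2 adjusted over the list alone), with the tight junction gene OCLN at 0.67 ± 0.06. These calls, and that of fatty acid synthesis (9 higher, 2 lower of 15; 9 and 2 adjusted over the list alone), held with an estimated correlation. The nuclear respiratory chain (20 of 31 lower, 24 adjusted over the list alone) was lost with adjusted p = 0.187 with an estimated correlation. AhR targets had 3 of 8 higher and no camera call (adjusted p = 0.0592), with CYP1B1 at 0.61 ± 0.04 and CYP1A1 at 0.10 ± 0.24 (adjusted p = 0.782).

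Between 190 and 7.6 µg/mL of Scutellaria 2560 genes were higher and 2583 lower, with STC2 at 2.16 ± 0.04, DDIT3 at 1.98 ± 0.07, CDKN1A at 0.52 ± 0.04 and HSPA1A at −1.30 ± 0.05. The ATF4 list rose in 25 of 27 (25 adjusted over the list alone) and p53 targets in 17 of 24 (18 adjusted over the list alone), and both calls held with an estimated correlation. At 38 µg/mL 563 genes were higher and 915 lower than in vehicle, and at 7.6 µg/mL 641 and 836. The cytosolic ribosome fell at 38 µg/mL in 28 of 35 members (34 adjusted over the list alone; adjusted p = 4.28e-41) and at 7.6 µg/mL in 19 (28 adjusted over the list alone; adjusted p = 4.04e-26), and both calls held with an estimated correlation. Ribosome genes were lower than in vehicle with every replicated extract at the low dose, from 8 of 35 members with dried ginger to 22 with Bojungikgi-tang and with Pinellia (25, 32 and 31 adjusted over the list alone). Of 178 genes called the same way at all 6 low doses, the 118 lower ones had a median exon length of 3374 bases and the 60 higher ones of 9824. DDIT3 fell at 38 µg/mL (−0.25 ± 0.08, adjusted p = 0.0495), opposite to the high dose. At the low dose of the other replicated extracts DDIT3 also lay below vehicle, from −0.11 with Pinellia to −0.19 with Sayeok-tang, not past the test. DDIT3 was −0.14 ± 0.08 and CDKN1A −0.10 ± 0.04 at 7.6 µg/mL, neither past the test. The medium-dose total of 1478 was 872 without its library 2 and 750 without vehicle library 3. The low-dose total of 1477 was 862 and 802 without its library 1 and 2 and 669 without vehicle library 3.

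Pinellia at 500 µg/mL had smaller changes against vehicle, 638 genes higher and 843 lower of 16582, 18 of them by at least 2-fold. Fibronectin (FN1) rose from 545 ± 7.96 to 672 ± 6.1 CPM (n = 3 each, log2 change 0.30 ± 0.03, adjusted p = 3.28e-07) and complement C3 by 0.27 ± 0.05. The ribosomal gene RPLP0 fell by 0.30 on the log2 scale, the cytochrome oxidase subunit COX7C by 0.31 and the succinate dehydrogenase subunit SDHD by 0.25. FN1, RPLP0 and SDHD were among the 178 genes called the same way at all 6 low doses, so their changes were not particular to Pinellia. The antioxidant genes HMOX1 (−0.18 ± 0.04), NQO1 (−0.14 ± 0.03) and GSTP1 (−0.21 ± 0.04) fell, and 0 of these 3 passed between the high and low dose of Pinellia. HMOX1 was also lower than in vehicle at the low dose of Sayeok-tang (−0.20 ± 0.04), Bojungikgi-tang (−0.17 ± 0.04), dried ginger (−0.18 ± 0.04) and Scutellaria (−0.18 ± 0.04). The cytosolic ribosome fell in 24 of 35 members (28 adjusted over the list alone; camera adjusted p = 5.79e-28), with 0 of 35 called between the high and low dose, and the nuclear respiratory chain in 13 of 31 (22 adjusted over the list alone; adjusted p = 1.43e-12). NRF2 targets fell in 7 of 25 with 2 higher (10 and 2 adjusted over the list alone). No list call of this comparison held with an estimated correlation: adjusted p = 0.0736 for the ribosome, and adjusted p = 0.0824 for the nuclear respiratory chain and for NRF2 targets, with an estimated correlation. CYP1A1 (−0.21 ± 0.24), CDKN1A (−0.06 ± 0.04), FKBP5 (0.00 ± 0.05), HMGCS1 (0.05 ± 0.04) and DDIT3 (−0.04 ± 0.08) did not pass. The total of 1481 was 714 and 800 without high-dose library 1 and 2 and 671 without vehicle library 3.

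The high and low doses of Pinellia differed in 11 genes, 10 higher and 1 lower. RGS2, which limits G-protein signalling, rose by 0.46 ± 0.07 (adjusted p = 0.00142) and the G-protein subunit GNG4 by 0.31 ± 0.06. TGF-beta and mesenchymal genes rose in 2 of 27 (12 adjusted over the list alone; adjusted p = 3.54e-13), which held with an estimated correlation. That total of 11 was 6 without high-dose library 1 and 2 without low-dose library 1. It was 29 by DESeq2, 21 in a fit of all 60 libraries, 56 with no filter on low counts, and 37 and 45 after removal of length and GC trends. At 100 µg/mL 471 genes were higher and 721 lower than in vehicle, and at 20 µg/mL 341 and 573. HMOX1 was −0.15 ± 0.04 and −0.19 ± 0.04 at these doses, past the test at both. The medium-dose total of 1192 was 744, 429 and 702 without its library 1, 2 and 3 and 443 without vehicle library 3. The low-dose total of 914 was 262 and 370 without its library 2 and 3, and 600 and 384 without vehicle library 2 and 3.

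**Figure D3:**
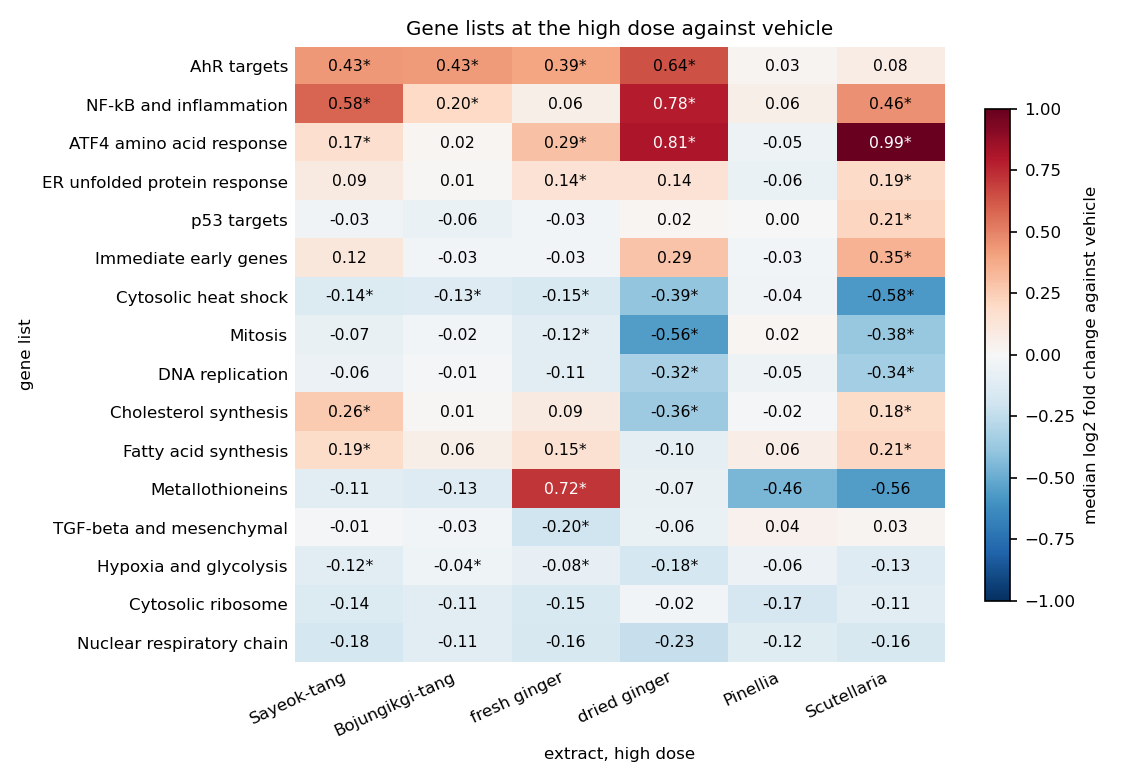
Median log2 change against vehicle at the high dose for 16 gene lists (vertical) and 6 extracts (horizontal), where colour gives the median and an asterisk marks a camera adjusted p under 0.05 with both the preset and the estimated correlation. The ATF4 median was 0.99 with Scutellaria and 0.81 with dried ginger, and the cholesterol synthesis median was 0.26 with Sayeok-tang and −0.36 with dried ginger.

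Markers of other cell types had no camera call at the high dose against vehicle. Fibroblast markers had 5 members tested, with camera adjusted p from 0.0506 with fresh ginger to 0.806 with Bojungikgi-tang, blood cell markers 3, and colon epithelium markers 5. The endothelial list had 1 member tested, the junction gene ESAM, which rose with Sayeok-tang (0.42 ± 0.11), dried ginger (0.50 ± 0.11) and Scutellaria (0.46 ± 0.11). The hepatocyte list had SERPINA1 alone, which did not pass with any of the 6 extracts. The interferon response, and lysosome and autophagy, had no camera call at the high dose against vehicle with any of them. The median and the mean differed in sign with dried ginger for the blood cell markers (−0.08 and 0.12) and the colon epithelium markers (0.27 and −0.07). Of the 30 lists, glucocorticoid receptor targets had a camera call with Sayeok-tang alone (4 higher, 7 lower of 19; 4 and 7 adjusted over the list alone), lost with adjusted p = 0.0573 with an estimated correlation. Mitochondrially encoded respiratory chain genes rose with Sayeok-tang in 6 of 13 (11 adjusted over the list alone), lost with adjusted p = 0.155 with an estimated correlation.

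Changes from the low to the high dose were compared between extracts of different fits, which share no libraries in these contrasts, a test chosen after the comparisons were seen. Dried ginger and Scutellaria both raised 1610 genes, where 435.1 would be shared by independent lists, and both lowered 1664 (416.1 for independent lists), with 77 changed in opposite directions. Sayeok-tang and dried ginger both raised 498 (108.1 for independent lists) and both lowered 441 (101 for independent lists). Across genes, which are not independent replicates, the log2 changes of dried ginger and Scutellaria had Pearson's r of 0.452 and Spearman's rho of 0.566.

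Coptis, an ethanol extract with 1 library per dose, was set against the 3 vehicle libraries by the size rule, which is not a test. At 110, 22 and 4.4 µg/mL 95, 40 and 22 genes lay higher beyond the rule and 77, 27 and 6 lower, of 10936 genes considered. A fit of all 60 libraries, which takes the spread from the replicated groups, called 5782, 3097 and 1316 genes at these doses, with no requirement on size. NIBAN1 was 101, 57.1 and 32.3 CPM at the high, medium and low dose against 10.5 ± 0.755 in vehicle, and STC2 164, 128 and 89.0 CPM against 28.2 ± 1.1. CYP1B1 was 216, 170 and 106 CPM against 55.5 ± 2.22. H19 was 20.6, 30.5 and 54.9 CPM against 84.1 ± 7.22 in vehicle, and NR4A1 had log2 ratios of −1.99, −1.61 and −0.75. GREM1 had ratios of 3.04, 2.06 and 1.15, and DDIT3 of 1.88, 1.48 and 1.04.

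The ATF4 list had a median log2 ratio of 1.05, 0.83 and 0.57 at the 3 doses of Coptis, with 15, 10 and 7 of 27 members beyond the size rule. Its median at the high dose lay at the 100th percentile of random lists, which were matched for size alone. Such a percentile can be high for a small median too. For mitosis with Zizyphus at the high dose it was 99.96 with a median of 0.039. With Coptis, mitosis had medians of −0.68, −0.37 and −0.21, with 30, 30 and 25 of 30 members below the vehicle range. Cholesterol synthesis had medians of −0.60, −0.47 and −0.32. The sterol sensor INSIG1, with ratios of −1.34, −1.01 and −0.70, lay below vehicle. The mitochondrial 12S ribosomal RNA (MT-RNR1, ENSG00000211459, mitochondrial chromosome, 648 to 1601) was 20998, 35199 and 24003 CPM against 1647 ± 100 in vehicle. The cytochrome oxidase mRNAs MT-CO1 (−1.13, −1.08 and −0.90) and MT-CO3 (−1.11, −1.35 and −1.27) lay below vehicle. Of 13 mitochondrial mRNAs 0, 3 and 5 lay above the vehicle range at the high, medium and low dose. MT-ND5 had ratios of −0.70, 0.92 and 2.16, MT-CYB of −0.69, 1.19 and 1.43, and MT-ND6 of −0.18, 1.09 and 1.85.

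**Figure D4:**
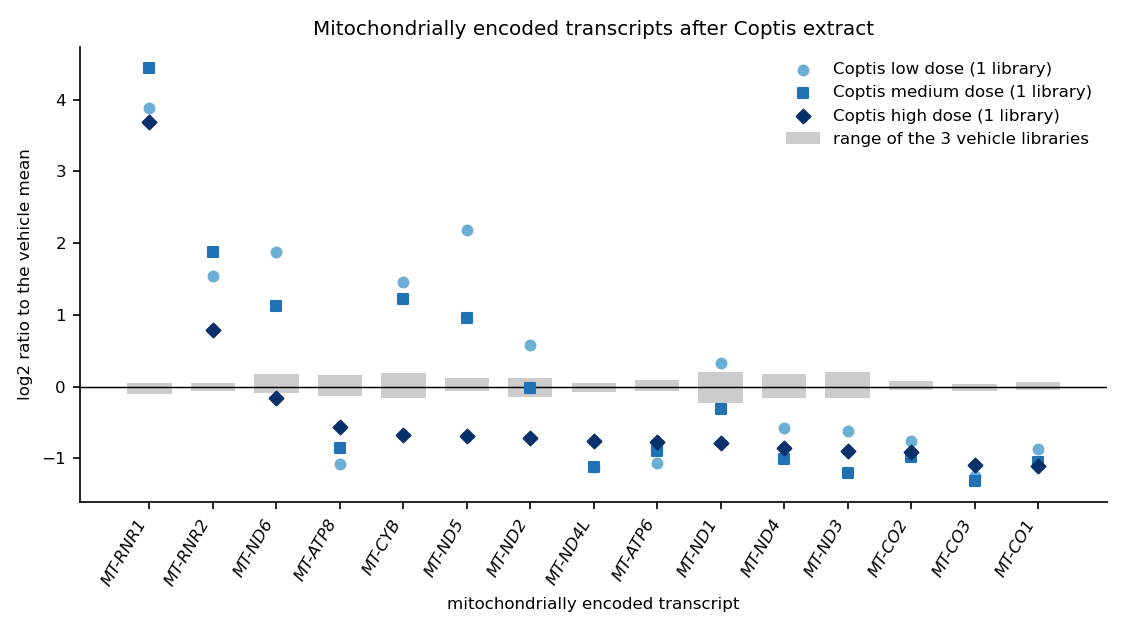
Log2 ratio to the vehicle mean of 15 mitochondrial transcripts in the Coptis libraries at 3 doses, 1 library each, with the range of the 3 vehicle libraries in grey, all scaled by TMM over the 60 libraries together. MT-RNR1 lay at 3.69, 4.45 and 3.89 at the high, medium and low dose, and MT-CO3 at −1.09, −1.32 and −1.25.

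Zizyphus, with 1 library per dose, had 10, 11 and 10 genes beyond the size rule at 500, 100 and 20 µg/mL, of 10916 considered, where the fit of all 60 libraries called 7, 9 and 136. Among the followed genes at 500 µg/mL, HMOX1 had a log2 ratio of −0.09, CDKN1A of −0.13, FKBP5 of 0.06, HMGCS1 of −0.03 and DDIT3 of −0.05. At the high dose the ATF4 list had a median of 0.01, cholesterol synthesis of −0.03 and mitosis of 0.04. At the high, medium and low dose the cytosolic ribosome had medians of −0.04, −0.16 and −0.19, with 14, 30 and 32 of 35 members below the vehicle range, and the nuclear respiratory chain of −0.04, −0.14 and −0.13 (12, 25 and 23 of 31 below). Mitochondrially encoded respiratory chain genes had medians of 0.04, 0.16 and 0.31, with 4, 6 and 12 of 13 above the vehicle range. The metallothionein list, here MT1X, MT2A and SLC30A1, had a median of −0.43 at the high dose, with all 3 members below the vehicle range. Its medians were −0.46 and −0.39 at the medium and low dose, and −0.10, −0.28 and −0.34 at the high, medium and low dose of Coptis. At the low dose of Pinellia the list, with 5 members tested, had a median of −0.45, whereas it rose with fresh ginger at the high dose. EIF3CL, a near-identical copy of a translation factor gene, had ratios of 2.87, 3.41 and 3.21 with Zizyphus and 3.62, 3.69 and 2.98 with Coptis, and reads are easily shared between such copies.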

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

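The tests of the differences between extracts in the change from low to high dose, of length and GC trends, of the handling of vehicle libraries, of mitochondrial DNA and of other splits of the libraries were chosen only after the result was seen. The gingers differed in how they changed from the low to the high dose: by edgeR's test of the interaction, 1866 genes of 16629 were called, 942 with a larger log2 change and 924 with a smaller one with fresh ginger. HMGCS1 differed by 0.72 ± 0.06 (adjusted p = 2.57e-09) and MT1X by 1.20 ± 0.18, and TRIB3 by −0.93 ± 0.08 and GREM1 by −0.94 ± 0.12, while MT2A (0.42 ± 0.24, adjusted p = 0.317) did not pass. The cholesterol synthesis list had a median difference of 0.347 (camera adjusted p = 2.67e-35), a call that held with an estimated correlation (adjusted p = 4.28e-07). For the formulas the same test called 46 genes of 16723, 27 with a larger and 19 with a smaller change with Sayeok-tang than with Bojungikgi-tang. Cholesterol synthesis had a median difference of 0.22 there (camera adjusted p = 8.95e-32; adjusted p = 3.03e-05 with an estimated correlation).

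The low doses of the 6 replicated extracts each differed from vehicle in 599 to 1477 genes in the fits per label set and in 669 to 2053 in 1 fit of all 60 libraries, and in that fit from each other in 0 to 18 genes (664 to 1504 at an unadjusted p under 0.05, 15 pairs). Thinning every library to the lowest total of its fit left at least 70.1% of the number of low-dose calls, not followed gene by gene. This argues against depth as the cause. Removing each library's length and GC trend left at least 50.3% of the same genes called, which argues against such a trend as the whole cause. That is only just above the bound set for this test, with Scutellaria keeping 743 of its 1477 calls and the median size of its called log2 changes going from 0.182 to 0.135, so a length trend stays open as part of the cause. Of 178 genes called the same way in all 6 comparisons, 71 were still called in all 6 after the removal, and the 60 higher ones had a median exon length of 9824 bases against 3374 for the 118 lower ones. Vehicle libraries handled apart from the extract libraries and an effect shared by any extract cannot be told apart, since no vehicle library shares a label set with an extract. The labels nevertheless put all 60 libraries in 1 named batch. Both explanations predict at most a few genes between low doses, of which the highest number was 18. A difference in DMSO between vehicle and extract libraries cannot be told apart from them either, since the sample labels give a concentration for the vehicle alone.

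Fresh ginger at 100 µg/mL had 128 calls, fewer than the 1077 at 20 µg/mL, and without library 2 of the medium dose it had 600. A length and GC trend in that library as the cause is argued against by the count after trend removal, which was 21.9% of the low-dose count (210 against 959). Low depth of that library is argued against by the low-dose count, which was 1043 when its own library 2 was thinned to the same depth. A vehicle library with a wrong label is argued against by TIPARP, 40.64 CPM in that library against 34.4 to 36.0 in vehicle, and by CYP1B1, 76.4 against 54.3 to 58.5. On the 178 shared genes its score was 0.045, just above the highest vehicle library (0.035) and below the other 56 extract libraries at 0.12 to 0.31, and what set this library apart stays open.

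The 12S ribosomal RNA of mitochondria lay 3.69, 4.45 and 3.89 log2 units above vehicle in the 3 Coptis libraries (all 60 libraries scaled together), the 16S RNA lay 0.78, 1.88 and 1.54 above it, and MT-CO1 and MT-CO3 below vehicle. Carry-over of RNA without a poly(A) tail that takes in small RNAs is argued against by 2879 genes for small nuclear, small nucleolar and similar RNAs. Their summed CPM lay 0.362, 0.111 and 0.135 log2 units above vehicle at the high, medium and low dose (SD between vehicle libraries 0.086). The set held only 202, 148 and 154 counts in these libraries, and it does not cover carry-over confined to longer RNAs. Over the extract libraries its log2 ratio to vehicle ran from −0.953 (Sayeok-tang low-dose library 3) to 0.931 (Sayeok-tang high-dose library 3). Most libraries of both formulas and both gingers lay below vehicle. The SD between vehicle libraries therefore understates the spread between libraries, which weakens this test. That set of small RNAs was defined after levels in vehicle had been seen. It replaced an earlier test of the gap between 12S and 16S RNA that could not have excluded carry-over. Mitochondrial DNA in the libraries, which would raise all 13 mitochondrial mRNAs, is argued against as the cause of the whole pattern by at least 8 of them below the vehicle range at each dose, but for the 0, 3 and 5 above the vehicle mean at the high, medium and low dose it stays open. Each dose had 1 library and no biological explanation was tested, so an effect of the extract and a fault of this library set stay open, although Zizyphus of the same set had log2 ratios of −0.01, −0.05 and −0.04 for the 12S RNA.

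For each of 23 comparisons of 3 with 3 libraries there are 10 splits, too few for a share under 0.05. In 21 of them 1 split, the real one, gave as many calls, with real counts of 11 to 6678 and at most 7 in any other split. For fresh ginger at the medium dose 2 of the 10 splits gave as many calls as the real 128. The other, which put vehicle library 1 with medium libraries 1 and 3, gave 808, several times the real count. It differs from the real split by exchanging vehicle library 1 and medium library 2. It therefore cannot tell a structure other than treatment from medium library 2 standing apart. For fresh against dried ginger at the low dose the real count was 0 and so was the highest other, so all 10 splits gave as many. There edgeR had 471 of 16629 genes at an unadjusted p under 0.05, fewer than a share of 0.05 would give, and DESeq2 called 2.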

How the results depend on the processing

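The removal of length and GC trends was chosen after seeing the data; the other settings were chosen before. Named genes past the test kept their direction under size factors of relative log expression and under the block. They also kept it without the library whose absence raised the adjusted p most. Called lists kept their direction under an estimated correlation, the rotation test fry and the block. The other settings were compared by counts. Size factors of relative log expression moved none of the 28 counts beyond 1.5 times. For the counts that moved, the cause was not tested. DESeq2 gave 273 genes for fresh ginger medium, 29 for Pinellia high against low, and 151 and 2 for fresh against dried ginger at the medium and low dose. One fit of all 60 libraries gave 367, 107 and 759 for Bojungikgi-tang high, medium and low, 465, 2053 and 1010 for fresh ginger medium, low and high against low, 1800 and 1402 for dried ginger medium and low, 21 for Pinellia high against low, and 252 and 1 for fresh against dried ginger medium and low. With no filter on low counts there were 544 for Bojungikgi-tang medium, 197 for its high against low, 299 for fresh ginger medium, 976 for dried ginger low, 56 for Pinellia high against low, and 244 and 13 for fresh against dried ginger medium and low. Removing a single trend per library gave 511 for Bojungikgi-tang medium, 220 for fresh ginger medium, 37 for Pinellia high against low, and 123 and 3 for fresh against dried ginger medium and low. Removing an abundance-dependent trend gave 180 for Bojungikgi-tang high against low, 210 for fresh ginger medium, 45 for Pinellia high against low, and 3 for fresh against dried ginger low. For Coptis the size rule took in 266 genes with a mean of at least 1 CPM, and a fit of all libraries with a pooled spread 5782, 3097 and 1316 at the high, medium and low dose against 172, 67 and 28 by the size rule. For Zizyphus the former gave 27 at the high dose, and the pooled fit 7, 9 and 136 against 10, 11 and 10 by the size rule.

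With the replicate number as a block, fresh ginger medium had 232 calls and fresh against dried ginger medium 122; the other 26 counts stayed within 1.5 times. Of 568 results for named genes 4 lost their call: MT-ATP8 with Bojungikgi-tang high (adjusted p = 0.0704), RPL22P1 (adjusted p = 0.0706) and MT-ND4L (adjusted p = 0.0516) with Pinellia high, and GINS1 between the formulas (adjusted p = 0.0702). CDKN1A with Sayeok-tang high gained one (adjusted p = 0.0498). The 568 results include followed genes that had no call to lose. Of 112 list calls 1 was lost, TGF-beta and mesenchymal genes between the formulas (adjusted p = 0.0692). After group means were removed, 89 of 360 same-number pairs of libraries correlated above 0.1, with a mean of 0.023 and a highest of 0.534, and different-number pairs had a mean of −0.011. Since not every pair was above 0.1, the samples were taken to share only a number. With 360 pairs that bound could hardly be met, so it cannot show that there was no structure. Of 48 libraries 26 correlated best with libraries of their own number, against a mean of 15.9 over 1000 random renumberings within groups (p = 0.019). That test was chosen after seeing the data. Within a label set same-number pairs had a mean of 0.104 and different-number pairs of −0.051. A weak structure by replicate number therefore stays open. The labels carry the number across both extracts of a set and do not say what it stands for. The blocked counts stand beside the others here alone.

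Leaving out 1 library gave ranges as follows; where a group of 2 was left with 1, its spread was assumed to be that of the other groups. Sayeok-tang had 2228 to 3148 at the high dose, 836 to 2064 at the medium, 766 to 1742 at the low, and 876 to 960 for high against low. Bojungikgi-tang had 203 to 756, 15 to 475, 205 to 1484, and 24 to 75 in that order. Fresh ginger had 1319 to 1855, 52 to 600, 368 to 964, and 382 to 496. Dried ginger had 5682 to 5870, 417 to 934, 137 to 515, and 4547 to 4817. Pinellia had 671 to 1650, 429 to 1434, 262 to 1081, and 2 to 12. Scutellaria had 5772 to 6205, 750 to 1642, 669 to 1673, and 4364 to 4569. Fresh against dried ginger had 2868 to 3325 at the high dose, 33 to 220 at the medium and 0 to 0 at the low, and Sayeok-tang against Bojungikgi-tang 183 to 244. Without 1 vehicle library Coptis had 180 to 186 and Zizyphus 11 to 12. Of 168 such counts 65 moved beyond 1.5 times. Of 568 results for named genes, followed genes without a call included, 93 lost their call without at least 1 library. Thinning each fit to its lowest total left from 67.2% of the number of calls (fresh ginger medium) to 95.5% (Scutellaria high against low), leaving aside the comparison with 0 calls by edgeR. Of 112 list calls at the high dose, 63 held with an estimated correlation and 106 by fry. The 6 lost by fry were mitochondrially encoded genes with Bojungikgi-tang, fresh ginger and Pinellia, the nuclear respiratory chain in both comparisons between related extracts, and immediate early genes between the formulas (adjusted p = 0.0652 to 0.227).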

Other observations

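The comparisons of overlaps and of Coptis with the replicated extracts in this part were chosen only after the results were seen; the tests of RN7SL1 belong to comparisons fixed before. Genes called in the change from low to high dose were compared between extracts, where overlaps in calls carry no p-value. Sayeok-tang and fresh ginger both raised 180 genes (11.1 for independent lists) and both lowered 217 (12.4 for independent lists), and the gingers both raised 251 (48.2 for independent lists) and both lowered 276 (51.7 for independent lists). The formulas both raised 36 genes (1.6 for independent lists) and both lowered 67 (2.9 for independent lists), while their log2 changes across genes had Pearson's r of 0.071 and Spearman's rho of 0.218. Pinellia, with 11 calls, shared 0 higher, 0 lower and 1 opposite with fresh ginger, and 4 higher (1.5 for independent lists), 0 lower and 6 opposite with Scutellaria. Scutellaria and Sayeok-tang both raised 407 genes (98.8 for independent lists), with 74 changed in opposite directions.

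Coptis had 1 library per dose, and its difference between the high and low dose was set against those of the replicated extracts across 10936 genes, which are not independent. Pearson's r was 0.668 with dried ginger, 0.562 with Scutellaria, 0.514 with fresh ginger, 0.475 with Sayeok-tang, 0.294 with Bojungikgi-tang and −0.051 with Pinellia. Further genes of Coptis at 110 µg/mL with a large ratio were FGB (−1.64) and FGA (−1.48), chains of fibrinogen, and the glucose transporter SLC2A3 (−1.43). Cytosolic heat shock had a median of −0.43 with 17 of 18 members below the vehicle range, and DNA replication a median of −0.50 with 32 of 32 below.

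RN7SL1, an RNA of the signal recognition particle, had 28.5 ± 18.0 CPM in vehicle against 4.70 ± 1.91 with fresh ginger at the high dose (log2 change −2.65 ± 0.58, n = 3 each, adjusted p = 0.00728 by edgeR). It was also lower against vehicle with dried ginger at the high (−2.76 ± 0.57), medium (−2.91 ± 0.59) and low dose (−2.66 ± 0.57). The same held for Scutellaria at the high dose (−2.14 ± 0.44) and Sayeok-tang at the medium (−2.47 ± 0.605) and low dose (−2.59 ± 0.63). With Pinellia at the low dose the change was −1.98 ± 0.435. The lower values were thus not particular to 1 extract or dose. These comparisons use the same 3 vehicle libraries with their large spread and are not independent of each other. Mitochondrial transcripts took 9.92, 15.9 and 15.0% of counts in the Coptis libraries at the high, medium and low dose.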
